A study of Mus musculus with 96 samples.

How the data were processed

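Microglia, the resident macrophages of the brain, were measured by RNA sequencing in wild-type mice. Cells positive for CD11b and Fcrls and negative for Ly6C were sorted, and 1000 cells were lysed for each library, per the labels' protocols. The series' design text names Smart-seq2, a full-length protocol for small amounts of RNA whose original form does not mark strand. Whether strand was used in counting is not given in the sources used here. The labels give 2 ages (3 to 5 months, called young, and 20 to 22 months, called old), 2 treatments (abdominal surgery and control), 2 times (6 h and 48 h) and 2 brain regions (hemisphere and hippocampus). What the control animals underwent is not stated. The 96 libraries came from 48 animals, since the library names give the hemisphere and hippocampus libraries of one animal the same sort number. They form 16 groups of 4 to 9 animals.

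The deposited values are estimated counts per Ensembl gene model, in whole numbers, with one column per library and no pooling, per the file headers. The submitters' processing notes name the mouse build mm10, R 4.2.1 and DESeq2 1.36.0. The aligner, the counter and the annotation release are not given in the sources used here. Column totals differed between libraries, so no scaling to a common total was seen in the deposited values. In 6 libraries the low values did not run 1, 2, 3: values of 1 made up 4.11% to 24.7% of all values from 1 to 3, against at least 42.7% in each of the other libraries. These 6 are called stepped libraries below. They are young control hippocampus 6 h replicates 1 and 4, old surgery hippocampus 6 h replicates 5 and 6, old surgery hemisphere 6 h replicate 6 and old control hemisphere 6 h replicate 7. How these values arose is not given. They were used as deposited, already whole. The design had been written for raw counts, and the count test was kept because the values ran in steps of 1 in the other libraries.

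Total estimated counts per library ran from 1874168 to 3778939, with a median of 2703893. A group of 15 gene models, most of them repeat-like or ribosomal (such as Gm26870, Gm10800 and the rRNA model CT010467.1), held 53.05% to 81.2% of each total. Outside them the libraries held 465922 to 1500332 counts, and 20489 to 26722 gene models had a count above 0. At this depth a gene could rest on few counts. Fkbp5 at 13.2 CPM (counts scaled to a library total of 1e6) in old control hemisphere at 6 h, for example, rested on a mean of 31.5 counts per library. Of 54532 gene identifiers, 54409 matched the Ensembl annotation of the same build used here for symbols, biotypes and coordinates. The 123 without a match kept their identifiers and held 0.0266% of the counts. All columns of per-library values were used.

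The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM normalization, robust dispersion estimates, and the filterByExpr filter at a minimum count of 10. The Benjamini-Hochberg (BH) threshold was 0.05 over all genes tested in a comparison, and a gene past it is called. Hemisphere and hippocampus libraries of each time were fitted separately as 4 groups, which share one estimate of the spread. In each fit, surgery was compared with control at each age, old with young among controls, and the surgery effect between ages (old minus young). Regions were compared within animals, with the animal as a block. The surgery effect at 48 h was compared with that at 6 h over all 8 groups of a region. CPM values in the text are TMM-normalized, relative to the whole library, and given as mean ± SD. Fold changes are log2 values with their standard error (SE). Coordinates are 1-based on mm10.

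Named genes followed a rule fixed before the data were examined. For each comparison it takes the 8 called genes with the largest positive and the 8 with the largest negative fold change at a mean log2 CPM of at least 4, leaving out predicted, Rik and mitochondrial symbols. It adds every called member of a fixed gene list, and always P2ry12, Tmem119, Apoe, Il1b, Tnf, Fkbp5, Tsc22d3, Clec7a, Socs3 and Cdkn1a. Il1b stayed under the count filter. Any other gene named was chosen after its values were seen.

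The 32 gene lists were fixed at the same time: 19 programmes and 13 sets of markers of other cell types. The programmes were homeostatic microglia, disease-associated microglia, interferon-stimulated, cytokines and NF-kB, STAT3 and acute phase, glucocorticoid-induced, immediate early, heat shock, MHC and antigen presentation, cell cycle, complement and Fc receptors, lysosome and phagocytosis, cholesterol synthesis, lipid efflux and storage, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, unfolded protein and integrated stress response, and senescence. The markers were of border-associated macrophages, monocytes, neutrophils, T and NK cells, B cells, neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, endothelial cells, pericytes and smooth muscle, choroid plexus, and erythrocytes. Each list with at least 5 tested members was tested with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Some genes stand in more than one list.

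Alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, no filter on low counts and the replicate number as a block. Also planned were the sort number as a covariate, only animals within the sort numbers of the young animals, and no animal block for regions. An estimated correlation for the lists and each library left out in turn were planned too. For regions, the surgery effect between regions and the change over time, only young animals were left out. After the data had been seen, 4 settings were added: leaving out the 6 stepped libraries, leaving out the 15 largest models, limma's voom with sample weights, and a covariate for the share of counts in TEC models (Ensembl gene models that still await experimental evidence). A fit of counts summed over both regions of an animal was also added then. The pairing of regions comes from the labels, and the animal block and the sums rest on it. Libraries of one animal correlated with a median of 0.18 at 6 h (15 of 23 pairs above 0.1, other pairs -0.054). Of these 23 pairs 0 correlated best with each other, and other pairs reached 0.509. The values at 6 h thus give only a weak sign of the pairing. At 48 h the median was -0.003 (7 of 25, other pairs -0.005), which gives no sign of it. On simulated counts with 200 genes changed, the share of genes changed 4-fold that the test recovered is given with each comparison where it was simulated. It was not simulated for young animals in the surgery effect between regions and in the change over time.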

Results

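Microglia sorted from the hemisphere and the hippocampus of 48 mice were compared between surgery and control, between young (3 to 5 months) and old (20 to 22 months) animals, and between 6 h and 48 h. Homeostatic microglial genes had a median level of 730 per 1e6 counts outside the 15 largest gene models. The medians of the 13 marker lists of other cell types ran from 0.296 (erythrocytes) to 17.5 (choroid plexus), with neurons at 2.91, astrocytes at 4.2 and B cells at 16.9. Single markers stood higher, such as Trf (1083), Stab1 (748), Csf3r (532), Ttr (488) and Ighm (328). Within groups, the median correlation between replicate libraries ran from 0.799 to 0.893. Young groups held 4 animals each and old groups 7 to 9.

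Old hemisphere at 6 h gave the most calls of all surgery comparisons. Of the 33 genes that rose there, 5 belong to the fixed list of genes induced by glucocorticoids, the stress hormones of the adrenal. Fkbp5 encodes a co-chaperone that restrains the glucocorticoid receptor, and Tsc22d3 encodes the glucocorticoid-induced leucine zipper, an inhibitor of inflammatory transcription. Ddit4 encodes an inhibitor of the growth kinase mTORC1. Among the genes that fell, Relb encodes a subunit of NF-kB, and Il6st encodes gp130, the signalling chain shared by receptors of the IL-6 family.

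Of 12760 genes tested in old hemisphere at 6 h, edgeR called 33 higher and 10 lower after surgery (BH below 0.05), and 1031 had an unadjusted p below 0.05. Fkbp5 (chr17:28399094-28517527) rose from 13.2 ± 2.44 to 69.1 ± 18.2 CPM, a log2 fold change of 2.39 ± 0.24 (edgeR BH 3.35e-06). Rcan1 (chr16:92391953-92470867), an inhibitor of the phosphatase calcineurin, rose from 8.01 ± 1.72 to 33.7 ± 10.7 CPM. Ddit4 (chr10:59949669-59951834) rose from 0.346 to 10.4 CPM. For Fkbp5, Rcan1, Ddit4 and Tsc22d3 all 7 surgery libraries lay above all 8 controls. Sult1a1, a phenol sulfotransferase, rose from 25.4 ± 6.62 to 70.2 ± 13.8 CPM. Tsc22d3 (chrX:140539528-140600659) rose from 24.9 to 93.5 CPM (1.91 ± 0.26). Zbtb16, a zinc-finger repressor, rose by 4.28 ± 0.84 from a mean of only 0.5 counts per control library. Bmf, which promotes cell death by binding BCL2 proteins, rose by 2.17, with 1 surgery library below every control. Tagap, a GTPase-activating protein of leukocytes, rose by 1.30, Ppp1r21, which serves endosomal sorting, by 1.45, and Rbm47, an RNA-binding protein, by 1.35.

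**Figure D1:**
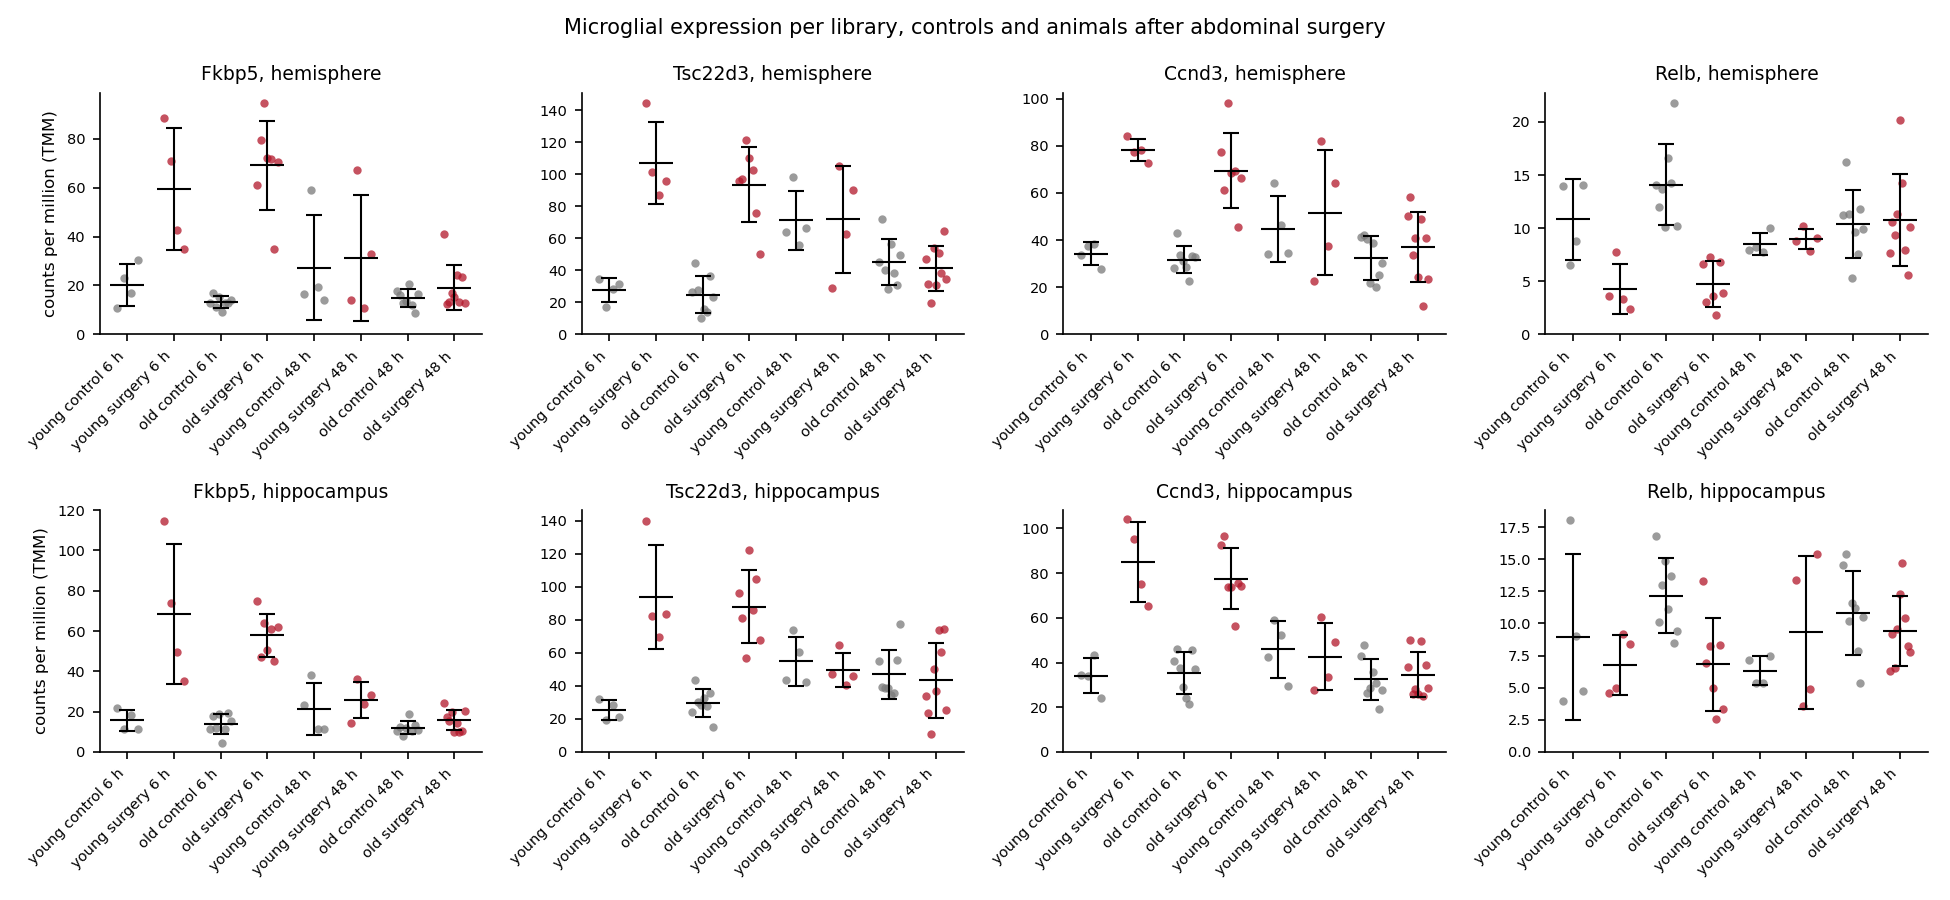
CPM of Fkbp5, Tsc22d3, Ccnd3 and Relb in each library, by region, time, age and treatment. Points are libraries, bars are means with SD, red is surgery and grey is control.

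Further called genes of old hemisphere were picked after their values were seen. Ucp2, a mitochondrial carrier, rose by 1.13 ± 0.15 (edgeR BH 0.000128), and Ccnd3, a cyclin of the G1 phase, from 31.7 to 69.5 CPM. Pik3ip1, an inhibitor of PI3-kinase, rose by 2.72 ± 0.43, Il15ra, the IL-15 receptor alpha chain, by 1.59, and Glul, glutamine synthetase, by 0.99. Ncf1, a subunit of the phagocyte NADPH oxidase, rose by 0.72 and Picalm, which assembles clathrin coats, by 0.71. Relb (chr7:19606217-19629438) fell from 14.1 ± 3.79 to 4.74 ± 2.17 CPM (-1.57, edgeR BH 0.0113), and all 7 surgery libraries lay below all 8 controls. Il6st fell from 56.4 to 26.0 CPM (-1.12), Cyb561a3, a lysosomal iron reductase, from 34.6 to 15.9 CPM (-1.12), and Asb2, an E3 ligase adaptor, from 21.6 to 10.8 CPM. Usp35, a deubiquitinase, fell by 0.97 and Rasa4, an inhibitor of Ras, by 0.77. Ighm, the immunoglobulin mu chain, fell by 1.34 from 134 ± 112 CPM, a control mean raised by 1 library. P2ry12, the purinergic receptor of resting microglia, stood at 433 CPM in controls and 318 after surgery without being called (-0.44, edgeR BH 0.134). Malat1, a nuclear RNA, held 0.414% ± 0.084% of the counts outside the largest models in controls and 0.528% ± 0.045% after surgery. Tmem119 (0.17), Tnf (-0.39), Clec7a (-0.93), Cdkn1a (-0.35), Apoe (-0.89) and Socs3 (0.74) were not called either. Without old surgery replicate 3 the count was 24. Among only the 3 old animals per group sorted alongside the young ones the count was 0. All 41 genes still tested kept their sign there. The genes had been called with these same libraries, so a kept sign is no independent support, here or in later refits. DESeq2 called 111 genes, and the test recovered 77.3% of simulated 4-fold changes.

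Young hemisphere at 6 h gave fewer calls, and all 7 that were higher were shared with old hemisphere. Tsc22d3 and Ddit4, both on the glucocorticoid-induced list, were among them. Ccnd3 and the sulfotransferase gene Sult1a1 were also among the shared genes.

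Of 12760 genes tested there, edgeR called 7 higher and 1 lower, with 564 at an unadjusted p below 0.05. Tsc22d3 rose from 27.8 ± 7.66 CPM by 1.94 ± 0.35 (above every control in 4 of 4 libraries, edgeR BH 0.0198). Ddit4 rose from 0.481 to 12.2 CPM (4.51 ± 0.76), Sult1a1 from 27.4 to 72.9 CPM (1.41), Ccnd3 by 1.19 and Mlph, an adaptor for melanosome transport, from 28.0 to 66.9 CPM (1.26). The other genes called higher were AC154912.1 and AC154912.3, gene models inside introns of Fkbp5. Fkbp5 itself went from 20.3 ± 8.46 to 59.2 ± 24.9 CPM and missed the threshold (1.54 ± 0.32, edgeR BH 0.0713). All 7 genes called higher were also called higher in old hemisphere, where 0.0181 would be shared by chance (Fisher p 3.92e-19). This p takes the genes as independent, although the 2 intronic models lie in one gene. Both comparisons also share one estimate of the spread. Phf6, a chromatin reader picked after its values were seen, fell by 2.44, but its control mean of 16.9 ± 13.1 CPM was uneven. P2ry12 (-0.55, edgeR BH 0.572), Tmem119 (0.17), Apoe (0.06), Tnf (0.26), Clec7a (-0.37), Socs3 (0.18) and Cdkn1a (-0.48) were not called. The count was 0 without young surgery replicate 1 or 3 or without young control replicate 2, 3 or 4, it was 4 without young control replicate 1, and DESeq2 called 24. Of simulated 4-fold changes the test recovered 45.5%.

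The hippocampus shared part of this response at 6 h. In old hippocampus, 10 of the 11 genes called higher were also called higher in old hemisphere, among them Fkbp5, Tsc22d3 and Ddit4. Nuak2, a kinase related to AMPK, was the other. Young hippocampus called 5 genes, 4 of which were shared with old hippocampus.

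In old hippocampus edgeR called 11 of 13703 genes higher and 1 lower (1134 at an unadjusted p below 0.05). Ddit4 rose from 0.766 to 12.9 CPM (4.01 ± 0.48), Fkbp5 from 13.9 to 57.9 CPM (2.06 ± 0.26, edgeR BH 0.000169) and Tsc22d3 from 29.6 to 87.8 CPM (1.57 ± 0.21). Ppp1r21 rose by 1.53, Ccnd3 by 1.14, Mlph by 1.04 and Tagap by 0.97, and Nuak2, picked after its values were seen, by 1.57. Rcan1 rose from 13.2 to 34.0 CPM. Cyb561a3 fell from 38.5 to 17.0 CPM (-1.19, edgeR BH 0.0363). In young hippocampus edgeR called 5 genes higher and 0 lower, with 1073 at an unadjusted p below 0.05. Tsc22d3 rose from 25.3 to 93.8 CPM (1.88, edgeR BH 0.00809), Fkbp5 from 15.7 to 68.4 CPM (2.11, BH 0.021), Ddit4 by 3.47 and Ccnd3 by 1.32, beside Gm10392, a model that overlaps Abhd15. P2ry12 (-0.38 in both ages), Tmem119, Apoe, Clec7a, Tnf, Socs3 and Cdkn1a were not called at either age. The old and young sets shared 4 genes, against 0.00401 by chance (Fisher p 1.12e-12), though both comparisons share one estimate of the spread. Of the 33 genes called higher in old hemisphere, 32 had a positive fold change in old hippocampus, from the same animals, with a median of 0.88. In old hippocampus the count was 7 without old surgery replicate 1 and 0 with only the 3 animals per group sorted alongside the young ones, where all 12 kept their sign. In young hippocampus it was 0 without young surgery replicate 1 and 0 without the stepped libraries, which leaves 2 controls and where all 5 kept their sign (median 1.96 against 1.88), 1 without surgery replicate 2, 2 without control replicate 2 or 4, and 1 in voom. DESeq2 called 64 genes in old and 29 in young hippocampus, 34 and 9 were called with no filter on low counts, and the test recovered 87.9% and 43.9% of simulated 4-fold changes.

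The glucocorticoid-induced list had the smallest adjusted p of all lists in the surgery comparisons at 6 h, and it passed with an estimated correlation each time. Its camera adjusted p was 5.95e-17 in young hemisphere, 1.4e-26 in old hemisphere, 1.67e-14 in young hippocampus and 6.85e-14 in old hippocampus. With an estimated correlation the values were 0.0012, 0.000112, 0.000299 and 0.000266. Of 15 tested members, 3, 5, 3 and 3 were called over all genes, and 8, 11, 9 and 6 when adjusted over the list alone, with medians of 0.89, 0.87, 0.75 and 0.34. Per1, a clock gene that glucocorticoids induce, had fold changes of 1.54, 1.08, 1.48 and 0.90 in that order, and Mt1, a metal-binding protein, of 0.89, 0.43, 0.66 and 0.17. In old hemisphere Nfkbia, which encodes an inhibitor of NF-kB (0.48), Dusp1, a phosphatase that turns off MAP kinases (0.56), and Hif3a (3.54) passed over the list alone. Cdkn1a went the other way in young hippocampus (-1.01) and passed over the list alone.

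**Figure D2:**
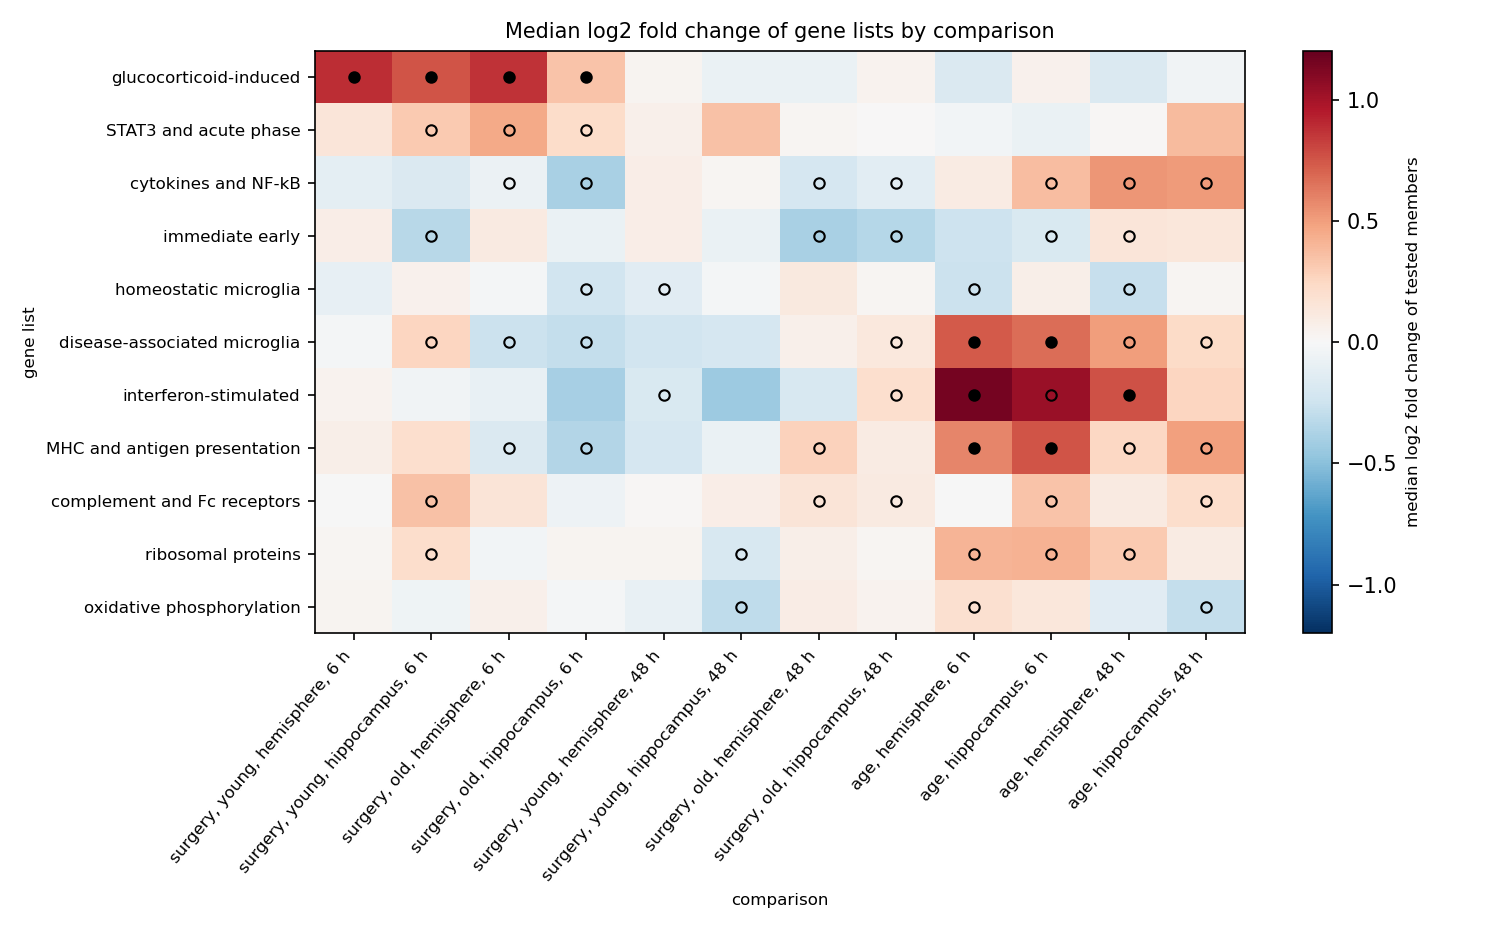
Median log2 fold change of 11 gene lists, chosen from the 32 after their results were seen, in the surgery and age comparisons. A filled dot marks an adjusted p below 0.05 with an estimated correlation, and an open dot marks one with the preset correlation only.

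In the surgery comparisons at 6 h, immune lists passed with the preset correlation only. In old hemisphere, cytokines and NF-kB lay lower (camera adjusted p 0.0106), and 3 of 17 members passed over the list alone. These were Relb, Nfkb2 (-0.80) and Tlr2, a receptor for bacterial lipoproteins (-0.93), against adjusted p = 0.334 with an estimated correlation. In old hippocampus the same list had a median of -0.39 (camera adjusted p 2.64e-05), with Nfkb2 at -1.02 passing over the list alone (adjusted p = 0.186 with an estimated correlation). The STAT3 and acute phase list lay higher in old hemisphere (camera adjusted p 0.00217), through Socs3 (0.74), Il4ra (0.61) and Il6ra (0.46) over the list alone. Its adjusted p was 0.0828 with an estimated correlation. It also lay higher in old hippocampus (camera adjusted p 0.0247), where Saa3, an acute-phase protein, stood at 1.14, and in young hippocampus (0.019). The adjusted p with an estimated correlation was 0.14 and 0.115.

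MHC and antigen presentation lay lower after surgery in old hippocampus (camera adjusted p 3.95e-05), where Tap2, a peptide transporter, and H2-K1 passed over the list alone (-0.92 and -0.56). In old hemisphere its value was 0.0389, with adjusted p = 0.672 with an estimated correlation there and 0.161 in the hippocampus. Disease-associated microglia lay lower in both old regions (0.000416 and 0.00726), with Lilrb4a, an inhibitory receptor, at -1.01 in hemisphere, and adjusted p = 0.347 and 0.409 with an estimated correlation. Homeostatic microglia lay lower in old hippocampus (1.96e-05, adjusted p = 0.409 with an estimated correlation), and in old hemisphere P2ry12 and Gpr34 (-0.53) passed over that list alone. In young hippocampus, ribosomal proteins (0.00364), complement and Fc receptors (0.00935), lysosome and phagocytosis (0.0307) and disease-associated microglia (0.0495) lay higher and immediate early genes (0.00935) lower. Each of these had adjusted p = 0.545 with an estimated correlation. Over the cytokine list alone Tnfaip3, Nfkb2 and Il1a passed as lower there, although the list as a whole did not (camera adjusted p 0.373).

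Age and surgery were tested together by subtracting the young surgery effect from the old one. The question is whether old microglia respond more, for example in the glucocorticoid-induced gene Fkbp5 or in Socs3, the feedback inhibitor of STAT3. At 6 h edgeR called 0 genes in the hemisphere (510 at an unadjusted p below 0.05, DESeq2 0, voom 0). Fkbp5 had an interaction of 0.85 ± 0.39 (edgeR BH 1), Socs3 of 0.56, Apoe of -0.95 and Tsc22d3 of -0.03. In the hippocampus edgeR called 0 genes (1273 at an unadjusted p below 0.05, voom 0), while DESeq2 called 6 higher and 9 lower, and edgeR 2 with no filter on low counts. Fkbp5 had -0.05 there and Tsc22d3 -0.31 ± 0.35. MHC and antigen presentation (median -0.47, camera adjusted p 0.00141) and disease-associated microglia (-0.48, 0.00242) lay lower in the hippocampal interaction, with adjusted p = 0.427 and 0.43 with an estimated correlation. Homeostatic microglia (0.00242), complement and Fc receptors, lysosome and phagocytosis and ribosomal proteins passed at the preset correlation too, and so did T and NK cells (median 1.08, 0.042). These 5 had adjusted p = 0.427 to 0.623 with an estimated correlation. In the hemisphere, disease-associated microglia (0.0312) and MHC and antigen presentation (0.0491) passed, both with adjusted p = 0.912 with an estimated correlation. The test recovered 27.3% of simulated 4-fold interactions in the hemisphere and 21.2% in the hippocampus, so only very large differences between ages would have been seen. Without old control replicate 2 the hemisphere count was 1.

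At 48 h edgeR called no gene after surgery. Fkbp5, the co-chaperone of the glucocorticoid receptor, and Tsc22d3, both called in old animals at 6 h, lay near control levels.

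At 48 h edgeR called 0 genes after surgery in all 4 comparisons. The counts at an unadjusted p below 0.05 were 440 in young hemisphere, 718 in old hemisphere, 731 in young hippocampus and 432 in old hippocampus. DESeq2 called 1 gene in old hemisphere and 0 in the other 3, and voom called 0 in each. Fkbp5 had fold changes of 0.20, 0.38, 0.27 and 0.40 in that order, and Tsc22d3 of 0.01, -0.12, -0.15 and -0.12. P2ry12, Tmem119 and Apoe also stayed within 0.40 of no change, and Tnf, Clec7a, Socs3 and Cdkn1a were not called. Of the 31 genes called higher in old hemisphere at 6 h and tested at 48 h, 22 were still positive, with a median of 0.14. Immediate early genes, which follow cell stimulation, lay lower in old hemisphere (median -0.39, camera adjusted p 1.58e-11) and old hippocampus (-0.34, 1.58e-09), with adjusted p = 0.451 and 0.475 with an estimated correlation. All 20 tested members were negative in old hemisphere. Recovery of simulated 4-fold changes was 57.6%, 86.4%, 62.1% and 89.4% in the same order. For 2-fold changes it was only 3%, 40.3%, 14.9% and 43.3%, so smaller effects could be missed. Refits without young control replicate 1 or 4, and without old control replicate 2, 3 or 5, called 1 gene in young and old hemisphere.

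Other lists passed at 48 h only with the preset correlation. In old hemisphere, MHC and antigen presentation (median 0.27, camera adjusted p 0.000616), lysosome and phagocytosis (0.00344) and complement and Fc receptors (0.0337) lay higher, and cytokines and NF-kB (0.00627) and heat shock (0.00686) lower. In old hippocampus, complement and Fc receptors (0.000746), disease-associated microglia (0.00427), interferon-stimulated genes (0.0169) and lysosome and phagocytosis (0.0169) lay higher. There UPR and ISR genes (0.00914), heat shock (0.0131) and cytokines and NF-kB (0.0236) lay lower, with adjusted p = 0.475 to 0.533 with an estimated correlation. In young hippocampus oxidative phosphorylation (0.00015), ribosomal proteins (0.000279) and glycolysis and hypoxia (0.00477) lay lower, with adjusted p = 0.456 for the first and 0.815 for the second with an estimated correlation. In young hemisphere heat shock (0.0226), interferon-stimulated genes (0.0365), glycolysis and hypoxia (0.0365) and homeostatic microglia (0.0499) lay lower, each with adjusted p = 0.827 with an estimated correlation.

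The interaction of age and surgery at 48 h also gave 0 calls in edgeR, DESeq2 and voom, with 589 genes at an unadjusted p below 0.05 in the hemisphere and 634 in the hippocampus. Fkbp5 had 0.17 and 0.13 and Apoe 0.42 and 0.65. At the preset correlation 9 lists passed in the hemisphere, led by immediate early genes (median -0.40, camera adjusted p 1.83e-06), and 6 in the hippocampus, led by oxidative phosphorylation (0.35, 0.000558). These leading lists had adjusted p = 0.637 and 0.576 with an estimated correlation. Recovery of simulated 4-fold interactions was 31.8% and 53%.

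The fading of the response can be tested directly by subtracting the surgery effect at 6 h from that at 48 h. In old hemisphere the glucocorticoid-induced genes Fkbp5 and Tsc22d3 lost their rise between these times. Relb and Asb2, which lay below control at 6 h, came back.

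In old hemisphere edgeR called 9 of 14144 genes higher and 15 lower in this difference, with 1045 at an unadjusted p below 0.05. Tsc22d3 had -2.04 ± 0.36 (edgeR BH 0.00972), Fkbp5 -2.02 ± 0.43, Rcan1 -1.93, Tagap -1.46, Rbm26 -1.23 and Ddit4 -4.69. Hif3a, a hypoxia-inducible factor, had -4.80 and Txnip, an inhibitor of thioredoxin, -0.79. Relb had 1.63 ± 0.36, Ighm 1.55, Cyb561a3 1.35 and Asb2 1.16. Il4i1, an amino acid oxidase of myeloid cells (2.41), and Il15ra (-1.68), both called, were picked after their values were seen, and 83.9% of the exonic bases of Il4i1 overlap Tbc1d17. With no filter on low counts the count was 5 (4 shared), DESeq2 called 49, and the test recovered 53% of simulated 4-fold differences. In old hippocampus edgeR called 0 of 14510 genes (1009 at an unadjusted p below 0.05, DESeq2 4), where Fkbp5 had -1.64 and Tsc22d3 -1.66, both at BH 0.101, and recovery was 45.5%. In young hippocampus it called 0 (1191 at an unadjusted p below 0.05, DESeq2 1), with Tsc22d3 at -2.06. In young hemisphere only Gclm was called (-7.99 ± 1.43, edgeR BH 0.0177, 610 at an unadjusted p below 0.05), and Tsc22d3 had -1.92 (edgeR BH 0.605). Gclm was called in 6 of 16 refits with a library left out, and young hippocampus gave 4 genes without young control replicate 3 at 6 h.

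Among controls at 6 h, the genes higher in old hemisphere include several of interferon response and antigen presentation. Apoe encodes the lipid carrier that disease-associated microglia make in quantity, and Lyz2 encodes lysozyme. H2-Aa and H2-Q7 encode MHC class II and class I chains, while Ifitm3 and Ifi27l2a answer interferon. These comparisons use the control libraries that also serve as reference for surgery, so they are not independent of it.

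In hemisphere at 6 h edgeR called 8 of 12760 genes higher and 2 lower in old controls (873 at an unadjusted p below 0.05). Apoe (chr7:19696109-19699188) rose from 81.8 ± 48.4 to 457 ± 172 CPM (2.49 ± 0.47, edgeR BH 0.0417), and Lyz2 from 52.8 to 129 CPM (1.28). H2-Aa (chr17:34282744-34287823) rose from 1.08 to 10.5 CPM (3.23 ± 0.64), H2-Q7 by 1.62, Ifitm3 by 2.62, Ifi27l2a from 3.29 to 17.8 CPM (2.43) and Lilrb4a from 2.17 to 12.1 CPM (2.46). All 8 old libraries lay above all 4 young ones for each of these. Fam20c, a kinase of secreted proteins (2.47), Phf6 (-2.33) and Ankrd26, an ankyrin-repeat protein (-3.39), were picked after their values were seen. Young levels of the last were 30.4 ± 32.5 CPM and rest on few animals. P2ry12 stood at 631 CPM in young and 433 in old controls without being called (-0.54, edgeR BH 0.194), and Clec7a at 2.67 and 19.0 CPM (2.85, BH 0.208). Fkbp5 (-0.62), Tsc22d3 (-0.17), Tnf (0.86), Socs3 (-0.38), Cdkn1a (0.15) and Tmem119 (-0.21) were not called. The count of 10 was 0 without young control replicate 2 or 4, 1 without young replicate 3, 6 without young replicate 1, 4 without old control replicate 5, and 2 without old replicate 1, 3, 6, 7 or 8. It was also 0 in voom and among animals sorted alongside the young ones, where all 10 kept their sign (median of the higher ones 2.03 against 2.47), and 2 without the stepped libraries (all 10 kept their sign, 2.43), while DESeq2 called 44. Recovery of simulated 4-fold changes was 62.1%.

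In hippocampus at 6 h edgeR called 5 of 13703 genes higher and 3 lower in old controls (1145 at an unadjusted p below 0.05). Upk1b, a tetraspanin, rose from 15.7 ± 4.48 to 54.9 ± 12.1 CPM (1.82 ± 0.30, edgeR BH 0.0099) and Lyz2 from 43.2 to 104 CPM (1.27). Ildr2, an immunoglobulin-domain receptor (2.68), Naalad2, a peptidase (2.29), and Tnfsf13b, the B-cell factor BAFF (1.71), rose too, and were picked after their values were seen. The same holds for Dag1, dystroglycan (-1.59), Upf3b, a factor of nonsense-mediated decay (-1.41), and Tgfb2, a growth factor (-4.96), which fell. Tgfb2 fell to a mean of 0.5 counts per old library. Apoe went from 89.9 to 361 CPM and missed the threshold (2.01 ± 0.44, edgeR BH 0.0964), as did Clec7a (2.62, BH 0.198). P2ry12 (-0.12), Tmem119 (0.21), Tnf (0.94) and Fkbp5 (-0.19) were not called. The count was 1 without young control replicate 1, 3 without old control replicate 1, 5, 6 or 7, 4 without old replicate 3, 5 without old replicate 2 and 19 without young replicate 3. It was 0 without the stepped libraries and among animals sorted alongside the young ones, where all 8 kept their sign (median of the higher ones 1.51 and 1.91 against 1.82), 1 in voom, 19 with no filter on low counts and 59 in DESeq2, with a recovery of 74.2%.

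**Figure D3:**
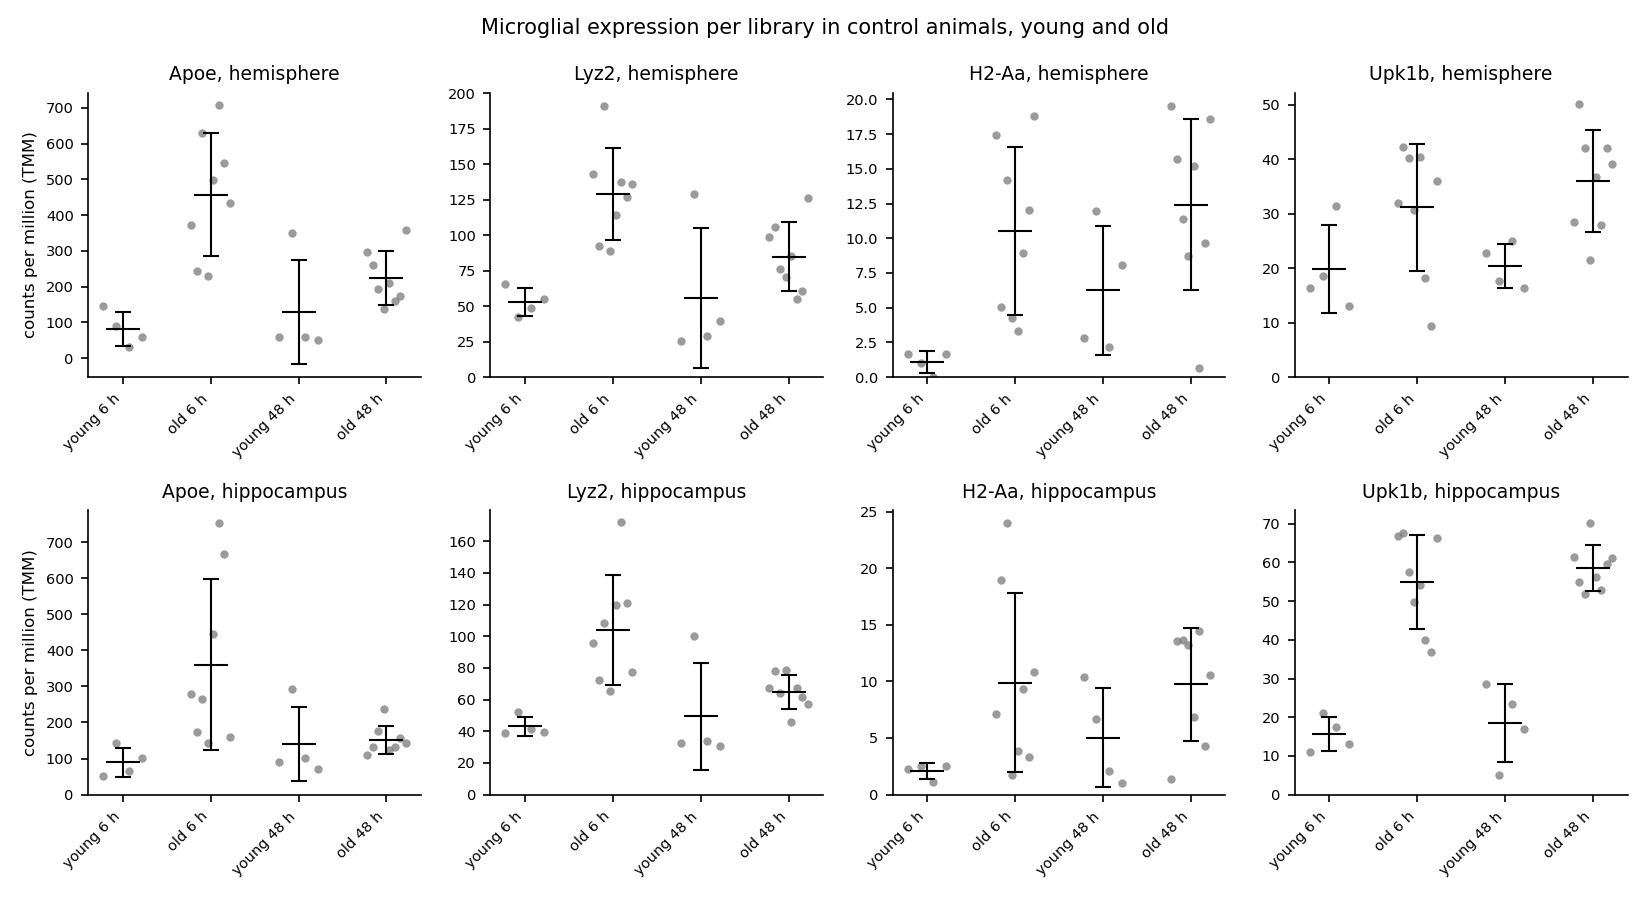
CPM of Apoe, Lyz2, H2-Aa and Upk1b in control libraries by age, region and time. Points are libraries and bars are means with SD.

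Age-linked programmes also passed as groups. Disease-associated microglia passed at 6 h in the hemisphere (23 members, median 0.73, camera adjusted p 1.03e-22, 0.00567 with an estimated correlation) and the hippocampus (22 members, 0.67, 1.2e-16, 0.0062). Of its members 3 and 1 were called over all genes, and 11 and 8 over the list alone, among them Cst7, a cathepsin inhibitor (3.47 and 2.94), Lgals3 (2.66 and 3.37) and Axl in the hemisphere (3.65). MHC and antigen presentation passed in both (16 members, medians 0.58 and 0.76, camera adjusted p 1.71e-15 and 1.54e-15, 0.0107 and 0.00506 with an estimated correlation). It had 2 calls over all genes in the hemisphere and 7 and 11 over the list alone, including Cd74, the invariant chain (1.98 and 1.89), and H2-K1 (0.79 and 0.92). Interferon-stimulated genes passed in the hemisphere (18 members, median 1.15, 6.65e-17, 0.0107 with an estimated correlation), with 2 called over all genes and 9 over the list alone, such as Bst2 (1.14). In the hippocampus 11 of 19 members were higher and 1 lower over the list alone (1.04, 1.18e-08), with adjusted p = 0.0807 with an estimated correlation. Mitochondrial genes held 1.04% ± 0.219% of the counts outside the largest models in old and 0.866% ± 0.119% in young control hemisphere at 6 h. In hippocampus they held 1.13% ± 0.146% and 0.834% ± 0.197%. Malat1 held 0.414% ± 0.084% and 0.523% ± 0.046% of the same counts in hemisphere and 0.505% ± 0.042% and 0.604% ± 0.157% in hippocampus.

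Ribosomal proteins lay higher with age at 6 h in the hemisphere (median 0.41, camera adjusted p 1.99e-15) and the hippocampus (0.42, 3.82e-15), each with 10 members over the list alone. Their adjusted p was 0.105 and 0.0807 with an estimated correlation. In the hemisphere homeostatic microglia lay lower (median -0.25, camera adjusted p 4.18e-10), P2ry12 passing over the list alone, and oxidative phosphorylation higher (0.0124). These had adjusted p = 0.118 and 0.557 with an estimated correlation. In the hippocampus complement and Fc receptors lay higher (5.3e-06), where C4b stood at 5.55 and passed over the list alone, with adjusted p = 0.105 with an estimated correlation. Cytokines and NF-kB (0.000256), lysosome and phagocytosis (0.000559), glycolysis and hypoxia (0.000559) and cell cycle (0.0314) lay higher there as well, and immediate early genes lower (0.0219). Their adjusted p was 0.142, 0.255, 0.107, 0.0807 and 0.566 with an estimated correlation.

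At 48 h the controls again differed by age. Cd52, a surface glycoprotein of leukocytes, and Lag3, an inhibitory receptor, were higher in old animals. Upk1b was the only gene called at both times in the hippocampus.

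In hemisphere at 48 h edgeR called 2 of 12250 genes higher and 9 lower in old controls (809 at an unadjusted p below 0.05). Cd52 rose from 8.43 ± 1.33 to 17.3 ± 2.83 CPM (1.03 ± 0.20, edgeR BH 0.0336) and Ildr2 by 2.01. Arsb, a lysosomal sulfatase, fell by 0.73 (BH 0.0491). The other genes that fell were picked after their values were seen. They include the unnamed models Gm42427 (145 to 46.9 CPM, -1.63 ± 0.18, BH 8.86e-06), Gm42031, Gm26880 and Gm43305, besides Gpr165, an orphan receptor (-1.87). Apoe (0.79, edgeR BH 0.784), Clec7a (2.12, BH 0.327), Tnf (1.43, BH 0.174), Cdkn1a (0.88), P2ry12 (-0.46), Tmem119 (-0.31), Fkbp5 (-0.88), Tsc22d3 (-0.66) and Socs3 (0.11) were not called. All 8 genes called higher at 6 h kept their sign at 48 h, with a median of 0.87. The count was 3 without young control replicate 3, 6 without young replicate 1 or old replicate 2 or 5, 7 without young replicate 4 or old replicate 3 or 8, 2 among animals sorted alongside the young ones and 19 in DESeq2. Recovery was 80.3%.

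In hippocampus at 48 h edgeR called 3 of 11985 genes higher and 7 lower in old controls (948 at an unadjusted p below 0.05). Upk1b rose from 18.5 to 58.6 CPM (1.66 ± 0.28, edgeR BH 0.00432) and Lag3 from 61.8 ± 6.65 to 113 ± 17.0 CPM (0.87, BH 0.026). Gm42427 (-1.24) and Gm42031 (-1.37) fell here as in the hemisphere of the same animals. Rgs7bp, a regulator of G-protein signalling (-2.56), Dynlt1b, a dynein light chain (-1.65), and Miga1, a mitochondrial fusion protein (-1.14), fell and were picked after their values were seen. Gclm fell by 3.65 from a young mean of 33.6 ± 57.5 CPM. Apoe (0.12), Clec7a (1.25), Tnf (1.63, edgeR BH 0.213), Cdkn1a (0.64), Fkbp5 (-0.84), Socs3 (0.64), P2ry12 (-0.03), Tmem119 (0.18) and Tsc22d3 (-0.23) were not called. Ttr, a choroid plexus marker, averaged 2141 ± 1713 in young and 410 ± 536 in old libraries, per 1e6 counts outside the largest models. The count was 23 without young control replicate 3, 3 among animals sorted alongside the young ones, 6 in voom and 22 in DESeq2. Recovery was 80.3%.

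Among lists at 48 h, interferon-stimulated genes passed in the hemisphere (21 members, median 0.77, camera adjusted p 5.64e-12, 0.0387 with an estimated correlation), with 8 over the list alone, such as Ifit3 (1.61). Cytokines and NF-kB lay higher in the hemisphere (median 0.53, 2.35e-11) and the hippocampus (0.51, 1.66e-09), with adjusted p = 0.0801 and 0.213 with an estimated correlation. Over the list alone 6 members passed in the hemisphere, including Ccl3 (1.10), Ccl4 (1.23) and Tnf, and 5 in the hippocampus, including Ccl3 (1.06), Tlr2 (0.97) and Nfkb2 (1.02). Disease-associated microglia lay higher (0.50 and 0.23, camera adjusted p 6.39e-08 and 0.000322), with 3 and 2 members over the list alone, Axl in the hemisphere at 2.12, and adjusted p = 0.108 and 0.257 with an estimated correlation. MHC and antigen presentation also lay higher (0.25 and 0.50, 0.00308 and 6.03e-06, adjusted p = 0.738 and 0.213 with an estimated correlation). Without young control replicate 2 the median of this list in the hemisphere was 0.58, and that of disease-associated microglia in the hippocampus 0.48.

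In the hemisphere homeostatic microglia lay lower (2.04e-09), ribosomal proteins higher (1.21e-11) and immediate early genes higher (0.0265), with adjusted p = 0.137, 0.108 and 0.839 with an estimated correlation. In the hippocampus complement and Fc receptors lay higher (0.0101) and oxidative phosphorylation lower (3.24e-05), with adjusted p = 0.455 and 0.213 with an estimated correlation. Ddit4 (-3.41), Per1 (-1.01) and Fkbp5 (-0.84) passed as lower over the glucocorticoid-induced list alone, though the list did not pass (camera adjusted p 0.207).

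No gene was called between hippocampal and hemispheric microglia of the same control animals. Homeostatic genes such as P2ry12, the purinergic receptor, and Tmem119, a surface protein of microglia, stood at similar levels in both regions. At 6 h edgeR called 0 of 14906 genes (774 at an unadjusted p below 0.05) and at 48 h 0 of 13473 (634), while DESeq2 called 19 and 0. P2ry12 differed by 0.03 and 0.24, Tmem119 by 0.03 and 0.05, Apoe by -0.21 and 0.01, Fkbp5 by -0.25 and -0.22, and Socs3 by -0.59 at 48 h (edgeR BH 0.973). Recovery was 89.4% and 78.8% of simulated 4-fold differences, but only 31.3% and 59.7% of 2-fold ones, so smaller differences could be missed. Without young control replicate 3 at 6 h the count was 4, it was 1 without replicate 2 or 4, and 1 without replicate 4 at 48 h. Without the animal block it was 2 at 6 h, and with no filter on low counts 92 genes were called at 6 h and 71 at 48 h.

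No gene's surgery effect was called different between regions either, including the glucocorticoid-induced genes Fkbp5 and Tsc22d3. EdgeR called 0 genes for young and old animals at 6 h (659 and 1041 at an unadjusted p below 0.05) and at 48 h (471 and 393). DESeq2 called 1 gene in young and 1 in old animals at 6 h and 0 at 48 h. In old animals at 6 h Fkbp5 had a difference of -0.26 ± 0.29, Tsc22d3 of -0.44 and Apoe of 0.77, and recovery was 45.5% at 6 h and 57.6% at 48 h. Without young control replicate 3 the young count at 6 h was 5, and without young control replicate 4 at 48 h it was 1. With no filter on low counts, 77 genes were called in young and 98 in old animals at 6 h, and 50 and 40 at 48 h.

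Ttr, the choroid plexus carrier of thyroid hormone, averaged 488 per 1e6 counts outside the largest models and ranged from 0 to 4687 between libraries. Over the choroid plexus markers alone Ttr was higher in old control hemisphere at 6 h (4.06), and Ttr (-4.76) and Enpp2 (-5.75) were lower after surgery in young hemisphere at 48 h. Kcnj13, a choroid plexus potassium channel, was lower in old control hippocampus at 48 h (-2.28). Oligodendrocyte markers lay lower after surgery in old hemisphere at 6 h (camera adjusted p 0.0217), where Mbp, myelin basic protein, stood at -1.36 and Cnp at -0.65. They lay higher in old control hippocampus (0.0488), with adjusted p = 0.147 and 0.105 with an estimated correlation. Monocyte markers lay lower after surgery in young hippocampus (0.029), where F10, coagulation factor X, stood at -1.94 and passed over the list alone, with adjusted p = 0.238 with an estimated correlation. T and NK cell markers lay lower with age in hippocampus at 6 h (0.0219, adjusted p = 0.105 with an estimated correlation).

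Over all comparisons without the sums over regions, 96 of 328 list tests passed with the preset correlation, 56 higher and 40 lower. With an estimated correlation 10 passed, all higher. Cholesterol synthesis (smallest camera adjusted p 0.142), lipid efflux and storage (0.141), senescence (0.121), B cells (0.672) and astrocytes (0.0723) never passed. Border-associated macrophages, neutrophils, neurons, oligodendrocyte precursors, endothelial cells, pericytes and smooth muscle, choroid plexus and erythrocytes never had 5 tested members there, so they were not tested as lists in these comparisons.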

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

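The tests of intronic gene models, of a linear trend with sort order, of the stepped libraries, of myeloid markers and of 1 young animal were chosen after the result was seen, as were the 3 patterns weighed here and the sums over both regions with their splits. The tests of sort order by range and of other splits for the remaining comparisons were not.

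Of 8 gene models that lie in introns of 3 genes called higher after surgery in old hemisphere at 6 h, 4 were called higher as well: AC154912.1, AC154912.3 and AC154912.5 inside Fkbp5 and Gm45221 inside Picalm. Over all 8 the median log2 fold change was 0.98, against 1.35 for the hosts, and 0.67 without the models of Fkbp5. Intronic models of genes that were not called had a median of -0.077 over 580 models, which argues against a rise of intronic models in general. Reads of the unspliced host transcript are a candidate explanation for this pattern. The 8 models include the 4 called ones that prompted the question, so their median is no independent support. AC154912.1 (1.2) lies on the strand opposite to Fkbp5. Host reads could count there if the libraries do not mark strand, as in the original form of Smart-seq2, or if counting ignored strand. Under this explanation the models may not be separate genes that respond to surgery. Whether strand was used in counting is not given.

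Members of the disease-associated, interferon and MHC lists were higher in old control hemisphere at 6 h, with a median of 0.79 over 57 members (95% interval 0.57 to 1.28), 55 of them positive. Intervals here and in the next paragraph resample the genes of a set, not the animals. They leave out the spread between animals, so what is argued from them holds for these animals only. With only the animals sorted alongside the young ones the median was 0.66. With the sort number as a covariate the median was 0.8 (interval 0.5 to 1.15). Both values argue against sort order as the whole cause. Without the stepped libraries the median was 0.8. Only 1 library compared here, old control replicate 7, is stepped, so that refit could change little and decides little about stepped values. Markers of monocytes and border-associated macrophages had a median of 0.22 (interval -0.54 to 0.8) over only 5 genes, so other myeloid cells stay open in the hemisphere, although the sort gate, negative for Ly6C and positive for Fcrls, is set against monocytes. In hippocampus at 6 h the median was 0.9. There the same markers had -0.31 over only 9 genes (interval -1.22 to 0.22), which gives no sign of other myeloid cells. The value of 0.84 with the sort covariate (interval 0.61 to 1.05) argues against a linear trend with sort order as the whole cause. Sort order of another shape (0.5 among animals sorted alongside the young ones, interval 0.41 to 0.72) cannot be told apart from age at this spread. The same holds for the stepped libraries (0.72, interval 0.45 to 0.86). Age itself remains the biological candidate explanation in both regions, as a hypothesis.

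Young control replicate 2 at 48 h resembled the old controls in some age-linked genes, and it was singled out after its values and the refits without each of the 24 control libraries at 48 h had been seen. On a scale from the other young controls (0) to the old controls (1), its median position was 0.66 in hemisphere (interval -0.04 to 0.94, 13 genes) and 0.42 in hippocampus (interval -0.19 to 0.92, 8 genes). The genes were called between the same libraries that set the ends, which widens the gap between the ends. Any young animal would therefore tend to lie above 0. In hemisphere Apoe (1.37), Lyz2 (1.47), Clec7a (0.91) and H2-Q6 (0.94) stood near old levels, while Gm42427 (-0.2), Gm26880 (-0.23), Gm43305 (-0.15) and Gm42031 (-0.04) stood at young ones. In hippocampus Gpr165 (2.41), Nos1ap (0.92), Gclm (0.79) and Ildr2 (0.78) lay near or past the old end. Gm27008 (-0.03), Gm42427 (0.06) and Gm42031 (-0.19) stood at young levels there, and Upk1b (-1.49) lay beyond the young end. An old animal under a young label and a young animal with an early age-linked programme cannot be told apart, because both intervals reach from below the young end to near the old end. Without this library the hemisphere medians at 48 h went from 0.77 to 1.14 for interferon-stimulated genes from 0.5 to 0.71 for disease-associated microglia and from 0.25 to 0.58 for MHC and antigen presentation, and in hippocampus from 0.26 to 0.46, 0.23 to 0.48 and 0.5 to 0.43, so it may hide part of the age difference.

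Values of single libraries far from the rest of their group were found in 2 of 48 library measures and 9 of 96 gene groups, where chance gives about 1 in 20. The 15 largest gene models held 71.04% of old control hippocampus 48 h replicate 5 (others 76.19% to 79.52%) and 53.05% of old surgery hippocampus 6 h replicate 5 (others 69.03% to 76.54%). Mlph stood at 86.62 CPM in young surgery hemisphere 6 h replicate 1 (others 58.85 to 62.17). In old control hemisphere at 6 h, Ighm stood at 408.3 CPM (others 76.26 to 133.3) and Ddit4 at 1.469 CPM (others 0 to 0.5376), both in replicate 3, and Bmf at 10.26 CPM in replicate 6 (others 4.82 to 7.005). In old surgery hemisphere at 6 h, Rbm47 stood at 66.73 CPM (others 17.21 to 35.93) and Ighm at 37.63 CPM (others 50.53 to 59.77), both in replicate 2, and Rasa4 at 19.26 CPM in replicate 3 (others 28.14 to 32.86). In old control hippocampus at 6 h, Ppp1r21 stood at 7.91 CPM in replicate 6 (others 16.48 to 24.21) and Cyb561a3 at 58.4 CPM in replicate 1 (others 26.82 to 40.59). The surgery effect differed between 48 h and 6 h, by a test of the difference, for 1 gene in young hemisphere and for 24 genes in old hemisphere.

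Other splits of the same libraries into groups of the same sizes were fitted for each count. For surgery at 6 h, as many genes as with the real groups came from 1 of 35 splits in young hemisphere (8 genes, highest other 0), 1 of 35 in young hippocampus (5, highest other 0), 1 of 100 in old hippocampus (12, highest other 2) and 3 of 100 in old hemisphere (43, highest other 331), the real split included. These 4 counts were thus rare among the splits, which makes chance unlikely but does not exclude it. In young animals 1 of 35 is the smallest share that the splits can give. The split that called 331 genes points to a structure of the old hemisphere samples beside surgery. For age, as many genes came from 1 of 100 splits in hemisphere at 6 h (10, highest other 3), 1 of 100 in hippocampus at 6 h (8, highest other 2), 1 of 100 in hippocampus at 48 h (10, highest other 8) and 2 of 100 in hemisphere at 48 h (11, highest other 41). These counts were rare among the splits too, and the split with 41 genes points to a structure of those samples.

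For the change of the surgery effect from 6 h to 48 h, 2 of 100 splits reached the 24 genes of old hemisphere. Such a count was rare, but the highest other gave 125 and points to a structure of the samples. The 1 gene of young hemisphere was not rare, since 14 of 100 splits reached that count (highest other 4). Every split reaches a count of 0 by construction, so the splits decide nothing there, and only the highest other value informs: surgery at 48 h in young hemisphere (35 of 35, highest other 1), old hemisphere (20 of 20, highest other 1), young hippocampus (35 of 35, highest other 4) and old hippocampus (20 of 20, highest other 0), the change over time in young (20 of 20, highest other 1) and old hippocampus (20 of 20, highest other 0), and the interaction of age and surgery in hemisphere at 6 h (highest other 0) and 48 h (1) and hippocampus at 6 h (1) and 48 h (1), each 20 of 20. The same holds for regions at 6 h (10 of 10, highest other 0) and 48 h (10 of 10, highest other 1), and for the surgery effect between regions in young and old animals at 6 h (highest other 0 and 1) and at 48 h (1 and 1), each 10 of 10. All of these are edgeR counts, whose counts at an unadjusted p below 0.05 and by DESeq2 stand with each comparison.

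With both regions of an animal summed, surgery at 6 h gave 12 genes in young (1 of 35 splits, highest other 1) and 63 in old animals (3 of 100, highest other 401), and age gave 30 at 6 h (1 of 100, highest other 3) and 35 at 48 h (2 of 100, highest other 186). These 4 counts were rare among the splits, and the splits with 401 and 186 genes point to a structure of the samples. For the summed counts of 0 the splits again decide nothing: surgery at 48 h in young (35 of 35, highest other 1) and old animals (20 of 20, highest other 2) and the interaction at 6 h and 48 h (20 of 20, highest other 1 each).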

How the results depend on the processing

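The settings without the stepped libraries, with the TEC share, without the largest models and with voom, and all sums over both regions and their listing by direction, were chosen after seeing the data. Under all settings together, values of named genes counted as the same 4995 times. Called genes then stayed called with their direction, and uncalled ones stayed uncalled and within their SE. Values fell short of the threshold 347 times, newly passed it 20 times and moved by over their SE without being called 115 times. Only genes called in the main fit could fall short, while the 4995 pool called and uncalled genes. These numbers thus give no rate of loss among called genes. None turned direction where the gene was called in either fit. Changes of sign in genes called in neither fit were not counted. RLE size factors and leaving out the 15 largest models moved no count of calls by over 1.5 times. The cause of a moved count was not tested, except that leaving libraries out lowers the number of animals. Small changes were seldom seen: at a fold of 1.5 the test recovered 0% to 10.4% of simulated changes. Counts are edgeR's unless named. DESeq2 counts follow the edgeR count, and other settings are given first, against the main count.

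DESeq2 gave more calls. For surgery at 6 h these were 8 and 24 in young hemisphere, 43 and 111 in old hemisphere, 5 and 29 in young hippocampus and 12 and 64 in old hippocampus, and 0 and 1 in old hemisphere at 48 h. For age they were 10 and 44 in hemisphere and 8 and 59 in hippocampus at 6 h, and 11 and 19 and 10 and 22 at 48 h. For the interaction in hippocampus at 6 h they were 0 and 15, for regions at 6 h 0 and 19, for the surgery effect between regions at 6 h 0 and 1 in young and in old, and for the change over time 24 and 49 in old hemisphere, 0 and 1 in young and 0 and 4 in old hippocampus. Summed over regions, higher and lower calls went at 6 h from 12 and 0 to 42 and 10 (young surgery), from 40 and 23 to 84 and 66 (old surgery) and from 25 and 5 to 84 and 21 (age), and at 48 h from 0 and 0 to 0 and 1 (young surgery), from 13 and 22 to 32 and 33 (age) and from 0 and 0 to 5 and 0 (interaction).

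Replicate numbers recur across groups. Same-numbered libraries of different groups had median correlations of -0.211 to 0.18, and in no comparison were all above 0.1. In none did every library correlate best with its own number, so they were not taken as pairs. At 6 h, however, the replicate number follows the sort order in every group, so the block there also stands for sort order. Calls lost with the block at 6 h may thus depend on sort order. At 48 h the numbers of old animals do not follow the sort order, so the block lacks this meaning there. With the replicate block the counts were 2 against 8 (young surgery) and 0 against 10 (age) in hemisphere at 6 h, 1 against 11 (age) and 1 against 0 (interaction) in hemisphere at 48 h, 7 against 12 (old surgery, 6 shared) and 2 against 8 (age, 1 shared) in hippocampus at 6 h, 0 against 10 (age) in hippocampus at 48 h, and 0 against 1 in young and 5 against 24 in old hemisphere for the change over time. The block moved no other count by over 1.5 times. Without the animal block, which is the "no replicate block" fit for regions, the count at 6 h was 2 against 0.

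Among only animals in the sort range of the young ones, where old groups hold 3 or 4 animals, old surgery at 6 h gave 0 against 43 in hemisphere and 0 against 12 in hippocampus. Age gave 0 against 10 and 0 against 8 at 6 h and 2 against 11 and 3 against 10 (2 shared) at 48 h. With the sort number as a covariate, age gave 2 against 10 and 7 against 11 in hemisphere and 4 against 8 in hippocampus at 6 h, and old surgery in hemisphere at 48 h gave 1 against 0. With the TEC share as a covariate, old surgery at 6 h gave 70 against 43 in hemisphere (42 shared) and 33 against 12 in hippocampus, age gave 5 against 10 (4 shared) and 5 against 8, and the hippocampal interaction gave 1 against 0. Voom gave 0 against 10 for age in hemisphere at 6 h, and in hippocampus 1 against 5 (young surgery), 20 against 12 (old surgery, 11 shared), 1 against 8 (age at 6 h) and 6 against 10 (age at 48 h).

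Without the 6 stepped libraries, which leaves 2 young controls in hippocampus at 6 h, age gave 2 against 10 in hemisphere and 0 against 8 in hippocampus, and young surgery in hippocampus gave 0 against 5. Surgery gave 10 against 8 (8 shared) in young and 49 against 43 (40 shared) in old hemisphere and 12 against 12 (9 shared) in old hippocampus, and the change over time in old hemisphere 23 against 24 (19 shared). Summed over regions at 6 h, higher and lower calls were then 4 and 2 (3 shared) for young surgery, 27 and 9 (31 shared) for old surgery, 2 and 0 (1 shared) for age and 0 and 1 for the interaction.

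With no filter on low counts, surgery gave 1 against 0 in young and in old hemisphere at 48 h, 9 against 5 (4 shared) in young and 34 against 12 (11 shared) in old hippocampus at 6 h, and age gave 7 against 11 (6 shared) in hemisphere at 48 h and 19 against 8 (6 shared) in hippocampus at 6 h. The interaction in hippocampus at 6 h gave 2, regions gave 92 and 71, and the surgery effect between regions gave 77 and 98 at 6 h and 50 and 40 at 48 h in young and old, all against 0. The change over time gave 0 against 1 in young and 5 against 24 (4 shared) in old hemisphere. For the list tests, 96 passed, 94 with RLE factors, 91 with the sort covariate, 78 without the stepped libraries and 10 with an estimated correlation.

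With each library left out in turn, surgery at 6 h ranged from 0 to 8 in young hemisphere, 24 (without old surgery replicate 3) to 51 in old hemisphere, 0 to 6 in young hippocampus and 7 (without old surgery replicate 1) to 16 in old hippocampus. At 48 h it ranged from 0 to 1 in both ages in hemisphere and stayed at 0 in hippocampus. Age ranged from 0 to 12 in hemisphere and 1 to 19 in hippocampus at 6 h, and 3 to 13 and 7 to 23 at 48 h. The interaction ranged from 0 to 1 in hemisphere at 6 h and stayed at 0 in the other 3 fits. For regions only the 4 young control animals of each time were left out, not the old ones. Those counts ranged from 0 to 4 at 6 h and 0 to 1 at 48 h. The surgery effect between regions in young animals ranged from 0 to 5 and 0 to 1. The change over time ranged from 0 to 1 in young hemisphere and 0 to 4 in young hippocampus. In old animals these 2 were not refitted this way. The 24 genes of the change over time in old hemisphere were thus not tested by leaving libraries out.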

Other observations

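The sums over both regions of each animal, and all genes named from them, were chosen after the result was seen.

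Summing the hemisphere and hippocampus counts of each animal adds calls to those of a region alone. In old animals at 6 h, 23 genes were called lower after surgery, 9 (7 shared) without the stepped libraries. Among them Cd83, a surface marker of activated antigen-presenting cells, fell by 0.87 ± 0.17, Tlr2 by 0.72 ± 0.16 (edgeR BH 0.035), and Cd180, a relative of Toll-like receptors, by 0.84. Nfkb2 fell by 0.89 (edgeR BH 0.0346) and Relb by 1.17, which together form the noncanonical NF-kB dimer, and Nrp1, a coreceptor for semaphorins and VEGF, fell by 0.93. Il4i1, an amino acid oxidase of antigen-presenting cells, fell by 1.76. Il6st, the gp130 chain, fell by 1.06 (edgeR BH 0.00213), while Lifr, the LIF receptor chain that pairs with it, rose by 0.92. Stab1, a scavenger receptor, rose by 0.76 ± 0.15 and Mrc2, a collagen receptor, by 1.26. In all, 40 genes were called higher by edgeR, 27 (24 shared) without the stepped libraries, and in young animals 12 higher, including Fkbp5 (1.84 ± 0.28) and Trpv4, a calcium channel (2.40). Without the stepped libraries the young count was 6 (3 shared). All 12 genes called in young and all 63 in old animals kept their sign there, and DESeq2 gave 150 genes in old and 52 in young animals. The glucocorticoid-induced list passed with an estimated correlation in young (0.000315) and old animals (4.93e-05). Cytokines and NF-kB lay lower in old ones (camera adjusted p 1.19e-05), as did MHC and antigen presentation (9.04e-06), both with adjusted p = 0.249 with an estimated correlation. Homeostatic microglia lay lower there too (median -0.13, camera adjusted p 0.000681, adjusted p = 0.572 with an estimated correlation).

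In old controls at 6 h the sums called more of the disease-associated programme. Cst7 rose by 3.21 ± 0.56 (edgeR BH 0.0128), Lgals3, a galectin, by 3.09, Clec7a, a receptor for fungal glucans, by 2.84 ± 0.58 and Axl, a receptor for dying cells, by 2.75. Cd74 rose by 1.98, H2-K1 by 0.88, H2-D1 by 0.91, Bst2 by 0.98 and Cd52 by 1.51. Of 25 tested members of the disease-associated list, 8 were called over all genes and 16 over the list alone (0.000301 with an estimated correlation). The interferon list had 3 and 16 of 24 (0.00273), and MHC and antigen presentation 5 and 11 of 17 (0.000472). Cell cycle genes lay higher (camera adjusted p 0.000924, 0.0209 with an estimated correlation). Oligodendrocyte markers lay higher (median 0.46, camera adjusted p 0.0187) and those of border-associated macrophages lower (-0.50, 0.0395), with adjusted p = 0.0992 and 0.0911 with an estimated correlation. At 48 h, Cxcl16, a chemokine that draws T cells, rose by 0.82 ± 0.16, Pdcd1, the inhibitory receptor PD-1, by 2.10 and Rxrg, a nuclear receptor, by 2.13. Cd52, Ildr2, Upk1b and Gm27008 were called higher at both times, in different animals, where 0.0218 would be shared by chance (Fisher p 4.33e-09). In old controls at 48 h, all 6 tested choroid plexus markers lay lower (median -0.60, camera adjusted p 0.00414, adjusted p = 0.406 with an estimated correlation). The age count at 6 h was 30, 2 without the stepped libraries, where all 30 kept their sign (median of the higher ones 1.40 against 1.74), and 84 higher and 21 lower in DESeq2.

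Some called genes share sequence with a neighbour or rest on few libraries. Of the exonic bases of Il4i1, 83.9% overlap Tbc1d17. The share is 50.98% for Gm10392 and 29.09% for Abhd15, which overlap each other, 35.32% for Lilrb4a (with Gm49339), 32.27% for Arsb (with Gm26527) and 23.25% for Tagap (with E430024P14Rik). It is 19.4% for Txnip (Gm15441), 15.24% for Cyb561a3 (Tkfc), 14.49% for Cd52 (Crybg2), 11.14% for Ncf1 (Gtf2ird2) and 11.04% for Ildr2 (5330438I03Rik). Samd12 in old control hemisphere at 6 h (11.8 ± 23.9 CPM), Ankrd26 in young control hemisphere at 6 h (30.4 ± 32.5 CPM) and Gclm in young control hippocampus at 48 h (33.6 ± 57.5 CPM) had a spread above their mean.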
